A study of Homo sapiens with 10 samples.

How the data were processed

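RNA levels were measured on 10 one-colour Agilent oligonucleotide arrays, one per sample, of human pluripotent stem cells in the naive state and of cells differentiated from them. Per the labels' protocols, naive cells were kept for 5 days in N2B27 medium with LIF at 10 ng/mL, the GSK3 inhibitor CHIR99021 at 1 µM, the MEK inhibitor PD0325901 at 1 µM and the protein kinase C inhibitor Gö6983 at 2 µM. The differentiated cells, called PrE in the labels, were kept for 7 days in RPMI medium with B27 lacking insulin, LIF at 10 ng/mL, CHIR99021 at 3 µM and activin A at 100 ng/mL. Cells grew either on mouse embryonic fibroblasts (MEF), a feeder layer, or on laminin-511 (LN511), a basement membrane protein used as a feeder-free coating. RNA was extracted with a column kit and DNase and labelled with Cy3, per the labels' protocols.

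The values of each array are spot intensities on a linear scale, deposited by the authors as written by Agilent Feature Extraction 12.0.1.1, which, per the file headers, subtracted the background and detrended the signal. No normalization between arrays had been applied to them. Whether a spot was well above background, saturated or an outlier is Feature Extraction's own call, per the file headers. A further table, deposited by the authors, holds log10 group means of their own normalized values. It also holds the p-value, the false discovery rate (FDR) and other scores of an analysis of variance over 4 groups that the authors ran, per the file headers; how its values were normalized is not given in the sources used here. That table was compared with the arrays and used in no test, because it has no value per sample.

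The log2 of the processed signal minus the array's 75th percentile was taken. Control spots and spots marked as outliers were left out, and spots of one probe were averaged, which gave 50599 probes. Probes were named through their RefSeq accession, without its version, in a table of genes of assembly GRCh38.p14. That named 28174 probes (55.7%) for 20503 symbols, and 22425 probes had no name in it. The array's grid was made on another assembly, so no coordinates are given. A gene entered the tests when a probe was well above background on every array of at least 1 of the 4 H9 groups, and the probe with the highest mean over all arrays stood for a gene with several. That left 15421 genes, of which 3761 had more than 1 passing probe, and in 11 of these the probes were called in opposite directions, none of them a gene named here. Values given for a gene's other measured probe come from the same fit run on all passing probes. The level of a gene that is not well above background on any array of a group is only a bound there. Its fold is given as "at least", the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. In the average over substrates, this holds for each group on its own. A group above background on only some of its arrays entered with its plain mean, dim signals included. With such a group, "at least" is not a strict lower bound. No fold is given where both groups were that dim.

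One model with a mean per group was fitted to all 10 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes), so the groups share one estimate of the spread, with 5 residual degrees of freedom and 3.20 prior ones. The 5 groups were H9 naive on MEF (3 arrays), H9 naive on LN511 (2 arrays), H9 PrE on MEF (2 arrays), H9 PrE on LN511 (2 arrays) and HNES1 PrE on MEF (1 array). The 7 contrasts were PrE minus naive in H9 averaged over the substrates, the same on MEF, the same on LN511, LN511 minus MEF in naive cells, LN511 minus MEF in PrE, the difference of the substrate-specific changes (interaction), and HNES1 minus H9 in PrE on MEF. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, and a gene was called below 0.05. The 27 gene lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. Data handling and figures used data.table, version 1.17.8, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 in Python 3.11.15.

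The design, the gene lists, most alternatives and the rule for named genes were set before the data were examined. The rule takes, per contrast, up to 4 called members of each list with the largest change. It adds up to 2 uncalled members of lists that did not move, the 10 largest rises and falls among called genes whose groups do not overlap and whose higher group is well above background on every array, and 15 fixed marker genes. Where under 5 genes were called, the 5 smallest p-values are given. Uncharacterised symbols were left out of the largest changes, and the way this was done also passed over numbered family symbols (FAM, KIAA, TMEM, CCDC and ZNF) and genes that code for no protein. A few members named beyond the rule are said to be so, and a few genes that the rule takes are not reported here.

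The procedure was tested on simulated data made from the real arrays' means and spread, with 200 of 15421 genes changed. Of genes changed 4-fold, 94% were recovered for the average over substrates, 61% on MEF, 36% on LN511, 51% for substrate in naive cells, 39% for substrate in PrE, 0% for the interaction and 0% for the line. Of genes changed 2-fold, 26% were recovered for the average, 2% on MEF and 0% elsewhere. Among the genes called, 8.7% on MEF and 7.3% for substrate in naive cells were unchanged ones, and at most 4.9% in the other contrasts. The test of lists recovered the 1 shifted list and called 0 of 26 unshifted ones. Genes were simulated independently of each other, with the same spread in each group. The simulation therefore cannot judge the list test for correlated genes or unequal spreads. In the real fits, 32.3% of genes were called for the average, 15.3% on MEF and 22.6% on LN511. This is a far larger share than was changed in the simulation. Benjamini-Hochberg adjustment depends on that share, so the percentages recovered are not the sensitivity of the real differentiation contrasts.

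Nothing in the labels says that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. The cell-line labels were taken as given and not tested, and genes of the Y chromosome and XIST were left out throughout. Of the arrays, 8 shared 1 slide and 1 scan day; naive MEF replicate 1 and the HNES1 array lay on slides of their own and shared another scan day. On the shared slide, MEF arrays lay in one row and LN511 arrays in the other, so slide row and substrate cannot be told apart.

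Alternatives tried were median centring, quantile normalization, no filter or a filter on all 10 arrays, only the shared slide, slide as a random block, replicate numbers as a block, array weights, a trended and robust prior, the mean over a gene's probes, a 2-fold minimum, fits on a comparison's own arrays, and leaving out each array in turn. Added after seeing the data were normexp (offset 50) on the median spot and background signals, since the files hold no mean signal, the HNES1 array pooled with H9 PrE on MEF, scan day as a block, and the gene lists under the shared slide, other normalizations and leaving out each array.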

Results

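Gene expression was profiled on 10 one-colour arrays in human embryonic stem cells of the naive state and in primitive endoderm-like cells derived from them. H9 is an established human embryonic stem cell line, and HNES1 is a line derived directly in the naive state. The H9 arrays comprised 3 of naive cells on a mouse embryonic fibroblast feeder layer (MEF), 2 of naive cells on laminin-511 (LN511), 2 of PrE on MEF and 2 of PrE on LN511. The HNES1 line was represented by 1 array of PrE on MEF. Per array, 42.7% to 66.6% of the 58717 non-control spots were well above background, the 75th percentile of signal ranged from 126 to 261, and 0 spots were saturated. Changes are given as log2 fold changes ± standard error with limma's adjusted p-value, between group means over the numbers of arrays just given.

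Arrays of one group resembled each other, with a lowest correlation across genes of 0.969 among naive arrays on MEF, 0.991 on LN511, 0.985 among PrE arrays on MEF and 0.923 on LN511. Genes are not independent replicates in such a correlation. The first principal component, which separated the naive arrays from the PrE arrays, held 59.9% of the variance over the 15421 genes tested, and the second held 12.3%. The PrE pair on LN511 had the widest spread, with a median standard deviation of 0.458 log2 units against 0.146 to 0.30 in the other replicated groups. Its replicate 2 had more POU5F1 signal (8.42 against 4.64 log2 units above the array's 75th percentile) and more NANOG signal (6.18 against 0.77) than replicate 1.

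The first comparison asked which genes change when naive H9 cells become PrE, averaged over both substrates (4 PrE arrays against 5 naive arrays). The endoderm transcription factors GATA6 and GATA4, which specify primitive endoderm, rose by 4.91 ± 0.20 (adjusted p = 6.84e-06) and 4.76 ± 0.34 (adjusted p = 5.05e-05). SOX17, an endoderm regulator, was at least 143-fold higher (adjusted p = 5.93e-05). FOXA2 rose by 4.70 ± 0.80 (adjusted p = 0.00316) and LHX1 by 8.68 ± 0.59 (adjusted p = 3.88e-05). SOX17 and FOXA2 were each measured above background on 2 of the 5 naive arrays, and LHX1 on 3. Of the 11 measured endoderm transcription factors, 8 rose, 1 fell and 2 did not pass; adjusted over the list alone, 10 rose and 1 fell. PRDM1, a zinc-finger repressor, was the one that fell (-1.69), named after its value was seen. HNF4A, a regulator of visceral endoderm and liver, had a value of 0.41 (adjusted p = 0.08). The list's median change was 3.67 (camera adjusted p = 4.11e-06, and adjusted p = 0.0331 with an estimated correlation).

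Surface and secreted proteins of the hypoblast, the human counterpart of primitive endoderm, also rose: 11 of 15 measured members rose and 1 fell (adjusted over the list alone, 12 and 1). PDGFRA, a receptor that marks hypoblast, rose by 5.42 ± 0.43 (adjusted p = 7.73e-05) and the cadherin CDH2 by 6.32. CER1, a Nodal and BMP antagonist, was at least 25.3-fold higher, and DKK1, a Wnt antagonist, at least 105-fold higher; neither was well above background on any naive array. The member that fell was PTH1R (-3.39), the parathyroid hormone receptor, named after its value was seen. Among basement membrane genes, 13 of 20 rose and 0 fell (the same adjusted over the list alone), including the collagen IV chains COL4A1 (4.56), COL4A2 (4.08) and COL4A6 (at least 27.7-fold; 1 of 5 naive arrays above background) and COL18A1 (4.38). The hypoblast list had a median of 2.71 (camera adjusted p = 1.09e-06, and adjusted p = 0.0331 with an estimated correlation), and the basement membrane list one of 1.94 (adjusted p = 1.09e-06, and adjusted p = 0.0272 with an estimated correlation). Of 16 measured yolk sac transport proteins, 4 rose, among them APOA2 (3.31), APOA1 (2.38), AFP (at least 5.34-fold) and RBP4 (at least 4.4-fold), and 5 fell; adjusted over the list alone, 6 rose and 5 fell (median 0.35, or 0.07 with dim genes at their bounds; camera adjusted p = 0.56). AFP and RBP4 were each above background on 2 of the 5 naive arrays, both on LN511.

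Genes of definitive endoderm and mesendoderm had the largest median change of the 27 lists. Of 14 measured members 13 rose, also adjusted over the list alone, with a median of 5.83, or 5.74 with dim genes at their bounds (camera adjusted p = 2.34e-10, but adjusted p = 0.0579 with an estimated correlation). GSC, a homeobox gene of the organizer, was at least 285-fold higher (adjusted p = 4.34e-05; 2 of 5 naive arrays above background), and CXCR4, a chemokine receptor used as a definitive endoderm marker, rose by 7.35. Of the T-box and homeobox regulators of the primitive streak, MIXL1 and TBXT rose by 5.65 and 5.82, and EOMES was at least 74.2-fold higher (2 of 5). Of 12 mesoderm genes 10 rose and 1 fell (adjusted over the list alone, 11 and 1; median 4.74, camera adjusted p = 2e-06, and adjusted p = 0.0331 with an estimated correlation). HAND1 (6.09), MESP1 (5.83) and MSX1 (5.09) rose, MSGN1 was at least 40.3-fold higher, and TBX6, named after its value was seen, was at least 1.44-fold lower and not well above background on any H9 PrE array. Several of these genes stood on more than 1 list: TBXT, MIXL1 and MESP1 counted as both mesendoderm and mesoderm, and SOX17, FOXA2 and LHX1 as both endoderm factors and mesendoderm.

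Targets of several signalling pathways rose as lists. The media differed in factors that act on such pathways: only naive cells had the MEK inhibitor PD0325901, while PrE had activin A and 3 µM CHIR99021 against 1 µM. Medium at harvest and cell state therefore cannot be told apart. By the probe used for each gene, the 16 measured targets of FGF/ERK signalling all rose, also adjusted over the list alone, with a median of 4.01 (camera adjusted p = 6.33e-12, and adjusted p = 0.0272 with an estimated correlation). DUSP6, a phosphatase that limits ERK, rose by 6.69 ± 0.37 (adjusted p = 1.96e-05), and IER3 by 5.39. EGR1 was at least 40.2-fold higher (2 of 5 naive arrays above background). SPRY4 was at least 49.3-fold higher, though its other measured probe had a value of -0.13 (adjusted p = 0.664). Of 12 Wnt targets 9 rose (adjusted over the list alone, 10 rose and 1 fell), including SP5 (5.92) and LEF1 (at least 77.4-fold; 2 of 5 naive arrays above background), with a median of 2.85, or 2.37 with dim genes at their bounds. The camera adjusted p for Wnt targets was 3.98e-07, and adjusted p = 0.0272 with an estimated correlation. Of 12 Nodal and activin targets 8 rose (adjusted over the list alone, 9; median 2.57, camera adjusted p = 2e-05, and adjusted p = 0.0331 with an estimated correlation). Of 9 BMP targets 7 rose (also adjusted over the list alone), with ID3 at 4.08 and SMAD6 at 3.63 (median 3.01, or 2.66 with dim genes at their bounds; camera adjusted p = 3.54e-05, and adjusted p = 0.0377 with an estimated correlation). Of 10 LIF/STAT3 genes 3 rose and 3 fell, also adjusted over the list alone: SOCS3 (4.74) and LIFR (3.38) rose while KLF4 and TFCP2L1 fell (median 0.02, camera adjusted p = 0.92).

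Naive pluripotency genes fell, while the list of core factors did not pass. Of 18 naive genes 0 rose and 11 fell (adjusted over the list alone, 14 fell; median -1.88, camera adjusted p = 2.37e-06, but adjusted p = 0.192 with an estimated correlation). KLF4 fell by 3.69 ± 0.19 (adjusted p = 1.49e-05), TFCP2L1 by 3.40, TFAP2C by 3.22 and OLAH by 4.97. KLF17, DPPA3 and DPPA5, markers of naive cells, had values of -0.23 (adjusted p = 0.533), -0.84 (adjusted p = 0.415) and -2.72 (adjusted p = 0.0584). Of 16 core pluripotency genes 3 rose and 2 fell, also adjusted over the list alone (median -0.08, camera adjusted p = 0.924). SOX2 fell by 2.70 ± 0.80 (adjusted p = 0.0335) and PRDM14 by 2.69, while TERF1 rose by 1.41 and SALL4 by 0.90. POU5F1 had a value of -1.06 (adjusted p = 0.248), while its other measured probe passed (-1.72, adjusted p = 0.0179), and NANOG had one of -1.98 (adjusted p = 0.134). Genes of the primed state rose in 12 of 15 cases (13 adjusted over the list alone), with SFRP2 at 6.05 and the surface protein THY1 at 5.95 (median 3.33, or 2.56 with dim genes at their bounds; camera adjusted p = 2.43e-08, but adjusted p = 0.132 with an estimated correlation).

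**Figure D1:**
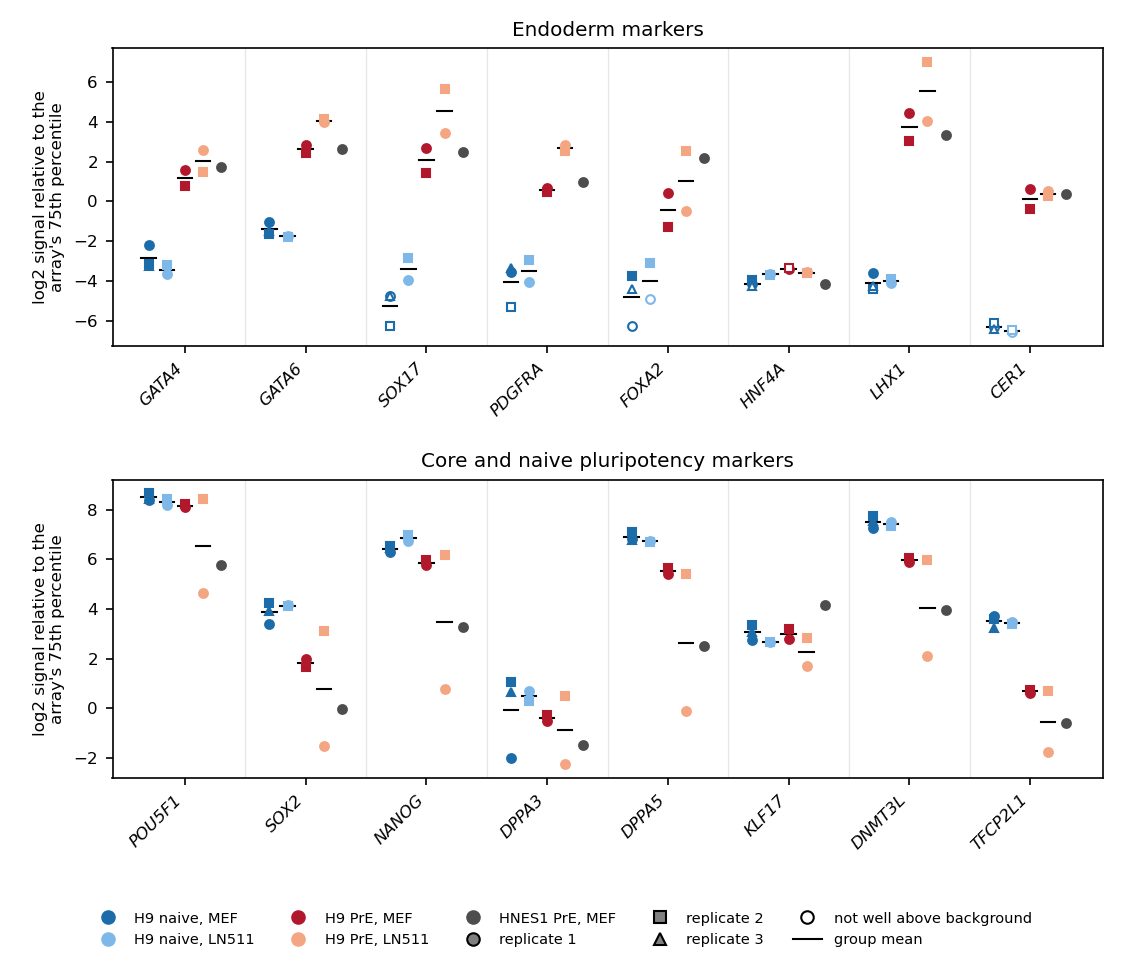
Log2 signal relative to each array's 75th percentile for 8 endoderm markers and 8 pluripotency markers, 1 point per array, coloured by group, with open symbols where the probe was not well above background and bars at group means. The endoderm genes GATA4, GATA6 and SOX17 are higher on each PrE array than on each naive array, while POU5F1 and NANOG lie far apart between the PrE replicates on LN511.

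Among other lineages, 3 of 4 amnion genes rose (4 adjusted over the list alone), with BAMBI at 3.01 and HEY1 at least 39.6-fold higher (1 of 5 naive arrays above background; median 3.47, or 3.20 with dim genes at their bounds; camera adjusted p = 0.000982, but adjusted p = 0.0882 with an estimated correlation). Of 19 fibroblast genes, kept as markers of the feeder layer, 11 rose and 2 fell (adjusted over the list alone, 12 and 3), with the filament gene VIM at 6.43, COL5A2 at 5.65 and PDGFRB at least 25.7-fold higher (1 of 5 naive arrays above background; median 1.80, or 1.04 with dim genes at their bounds; camera adjusted p = 0.000384, but adjusted p = 0.221 with an estimated correlation). Integrins and laminin receptors rose in 8 of 16 cases and 1 fell (also adjusted over the list alone), with ITGA5 at 3.92 and ITGAV at 3.83 (median 1.34, or 0.56 with dim genes at their bounds; camera adjusted p = 0.000138, and adjusted p = 0.0377 with an estimated correlation). Of 13 trophectoderm genes 4 rose and 4 fell, also adjusted over the list alone: HAND1 (6.09), CDX2 (3.38) and KRT18 (3.21) rose, and CGA, the alpha subunit of chorionic gonadotropin, was at least 9.78-fold lower (median 0.03, camera adjusted p = 0.916). CGA was above background on 2 of the 4 PrE arrays. Of 6 neuroectoderm genes 3 rose, among them LHX2 (4.39) and NCAM1 (at least 7.88-fold; 3 of 5 naive arrays above background), and adjusted over the list alone 3 rose and 1 fell (median 1.46, or 0.95 with dim genes at their bounds; camera adjusted p = 0.13). Epithelial-mesenchymal genes divided into 6 that rose and 3 that fell of 12, also adjusted over the list alone: CDH2 and VIM rose, SNAI2 was at least 14.1-fold higher, and the epithelial cadherin CDH1, named after its value was seen, fell by 1.35 (median 0.70, camera adjusted p = 0.0927).

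The lists of metabolism and stress did not pass in the chosen analysis. The glycolysis list did pass under median centring (camera adjusted p = 0.0494), quantile normalization (adjusted p = 0.0418) and normexp (adjusted p = 0.0284). Cholesterol synthesis genes rose in 5 of 17 cases (adjusted over the list alone, 5 rose and 1 fell; median 0.23, camera adjusted p = 0.13), and glycolysis and hypoxia genes in 6 of 17 with 1 fall, also adjusted over the list alone, led by the glucose transporter SLC2A3 at 3.12 (median 0.51, camera adjusted p = 0.0551). Of 20 cell cycle genes 2 rose and 3 fell (adjusted over the list alone, 2 and 2; median -0.04, camera adjusted p = 0.924). DNA methylation genes comprised 1 rise, DNMT1 (0.79), and 3 falls of 7, TET1 (-1.06; 1 of 3 probes did not pass, adjusted p = 0.0687), DNMT3A (-0.67) and DNMT3L (-2.47); adjusted over the list alone 2 rose and 4 fell (median -0.65, camera adjusted p = 0.622). Of the other measured probes of DNMT3A, 1 fell (-0.99, adjusted p = 0.0121) and 1 did not pass (0.54, adjusted p = 0.257). Of 8 interferon genes 0 rose and 2 fell, also adjusted over the list alone, including MX1 (-3.57; median -0.42, camera adjusted p = 0.348). Of 13 genes of endoplasmic reticulum and amino acid stress 0 rose and 4 fell, TRIB3 (-2.58), DDIT3 (-1.83), ASNS (-1.43) and CHAC1 (-1.13); adjusted over the list alone 5 fell (median -0.11, camera adjusted p = 0.625). Of 11 p53 and apoptosis genes 3 rose and 1 fell, also adjusted over the list alone (median 0.11, camera adjusted p = 0.492).

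Among the largest fitted rises over all genes were ERBB4, an ErbB receptor (9.41 ± 0.67, adjusted p = 4.81e-05; 2 of 5 naive arrays above background), CYP26A1, which degrades retinoic acid (9.29 ± 0.59, adjusted p = 2.87e-05; 3 of 5), WNT5A (at least 292-fold, adjusted p = 3.16e-05; 1 of 5) and the Wnt receptor FZD7 (at least 306-fold, adjusted p = 7.06e-06; 2 of 5). The tight junction gene CLDN11 was at least 101-fold higher. Among the largest fitted falls were the transcription factor SPIC (at least 87.7-fold lower), the integrin ITGAM (at least 35.0-fold), SLC7A4 (at least 23.3-fold) and NLRC4 (at least 15.3-fold), none of them above background on any of the 4 H9 PrE arrays. CD53 was at least 48.2-fold and GDPD2 at least 37.3-fold lower (each above background on 1 of 4 PrE arrays), and GPNMB fell by 5.80 and the metallothionein MT1G by 5.25. Among genes given with exact changes for the average, MIXL1, MSX1, SFRP2 and LHX2 were above background on 3 of the 5 naive arrays, and PDGFRA, CXCR4, DUSP6, MESP1, SMAD6, LIFR, THY1, APOA2 and HNF4A on 4. GPNMB, PTH1R, TFAP2C and HNF4A were above background on 3 of the 4 H9 PrE arrays. For COL4A6, EGR1, EOMES, FZD7, HEY1, LEF1, PDGFRB, WNT5A, CD53 and GDPD2, the "at least" fold of the average is not a strict bound. In each, a group above background on only some of its arrays entered with its plain mean. In all, 4979 of 15421 genes passed, 2387 higher and 2592 lower, and 3452 of them changed at least 2-fold; the median change over all genes was -0.12. Within the 8 arrays of the shared slide, 4956 genes passed, 4534 of them in common, and 14 lists passed, as over all arrays. There the value of GATA6 was 5.00 (adjusted p = 3.62e-05), of GATA4 4.92 (adjusted p = 0.000143), that of SOX2, -2.82, no longer passed (adjusted p = 0.0511), and SOX17 passed (adjusted p = 0.000284). Under normexp, chosen after seeing the data, the 14 lists passed too. Their medians were smaller there, such as 1.37 for endoderm factors (6 of 11 rose), 1.37 for primed, 1.38 for Wnt and 2.60 for mesoderm genes. Leaving out naive LN511 replicate 1 gave 3168 genes, and leaving out replicate 2 gave 3277.

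**Figure D2:**
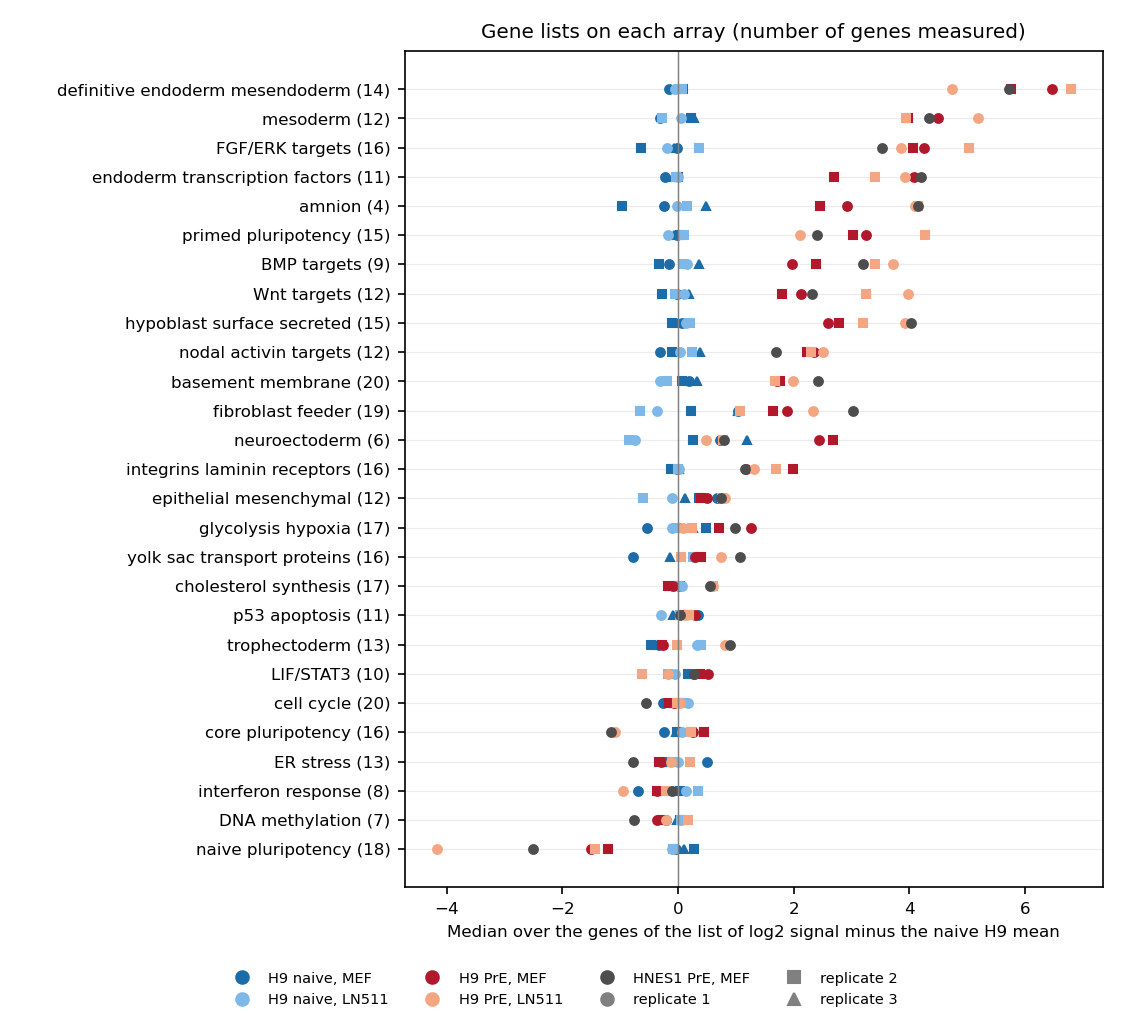
Median over each list's measured genes of log2 signal minus the naive H9 mean, 1 point per array, coloured by group and shaped by replicate. Mesendoderm, mesoderm, FGF/ERK target and endoderm lists lie to the right on each of the 5 PrE arrays, and the naive list lies to the left.

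On MEF, where 2 PrE arrays were compared with 3 naive arrays, the endoderm factors GATA6 (4.0 ± 0.26, adjusted p = 0.000216), GATA4 (4.05 ± 0.46, adjusted p = 0.00127), FOXA2 (4.37, adjusted p = 0.031) and the receptor PDGFRA (4.64) rose. Of 3 measured probes of GATA4, 1 did not pass on MEF (2.25, adjusted p = 0.241) or on LN511 (3.12, adjusted p = 0.115). SOX17 was at least 84.0-fold higher (adjusted p = 0.000871), GSC at least 262-fold, DKK1 at least 40.5-fold and CER1 at least 21.8-fold. The small GTPase RAB17 rose by 8.49, ERBB4 by 8.28, CYP26A1 by 7.98, LHX1 by 7.83, WNT5A by 7.77 and the neuropeptide NTS by 7.65. Of the naive MEF arrays, RAB17, ERBB4, WNT5A and NTS were above background only on replicate 3. LHX1 was so only on replicate 1, FOXA2 only on replicate 2 and CYP26A1 on replicates 2 and 3. These changes are therefore fitted partly to signals at background. POU5F1 (-0.34, adjusted p = 0.843), NANOG (-0.57, adjusted p = 0.808), SOX2 (-2.05, adjusted p = 0.245) and the collagen COL1A1 (-1.04, adjusted p = 0.168) did not pass, while KLF4 fell by 3.36 and TFCP2L1 by 2.83. Of 18 naive genes 6 fell (median -1.32). SPIC was at least 61.3-fold lower, GDPD2 at least 31.5-fold, CD53 at least 26.8-fold and ITGAM at least 17.6-fold, and TKTL1 fell by 5.51. In all 2353 genes passed, 1221 higher and 1132 lower. The lists that passed were the 14 of the average and glycolysis (adjusted p = 0.00324, but adjusted p = 0.266 with an estimated correlation), and 10 passed with an estimated correlation. On the shared slide alone 1799 genes passed, and FOXA2 no longer did (3.63, adjusted p = 0.0788). Leaving out naive MEF replicate 2 gave 1223 genes, PrE MEF replicate 1 gave 744, PrE MEF replicate 2 gave 673, and either PrE LN511 array gave 4152.

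On LN511, where 2 PrE arrays were compared with 2 naive arrays, GATA6 rose by 5.82 ± 0.29 (adjusted p = 5.09e-05), GATA4 by 5.46 ± 0.51 (adjusted p = 0.000371), SOX17 by 7.93 ± 0.84 (adjusted p = 0.000613), FOXA2 by 5.02 (adjusted p = 0.019) and PDGFRA by 6.20. FZD7 was at least 1002-fold higher, NOG, a BMP antagonist, at least 361-fold, LEF1 at least 214-fold, EOMES at least 180-fold, the defensin DEFA6 at least 172-fold and CER1 at least 29.3-fold. CYP26A1 rose by 10.59, ERBB4 by 10.54, LHX1 by 9.53, CDH2 by 8.26 and VIM by 8.20. Of the naive LN511 arrays, CYP26A1 and FOXA2 were above background only on replicate 2 and ERBB4 only on replicate 1. The naive factors TFAP2C (-5.27), KLF4 (-4.03) and TFCP2L1 (-3.97), the growth factor FGF4 (-4.70) and PRDM14 (-4.15) fell, and 9 of 18 naive genes did (median -2.48). The PrE arrays differed there: the median was -1.37 without replicate 1 and -4.14 without replicate 2. POU5F1 (-1.78, adjusted p = 0.218), NANOG (-3.39, adjusted p = 0.108) and DPPA5 (-4.07, adjusted p = 0.0706) did not pass, though the other measured probe of POU5F1 did (-3.17, adjusted p = 0.0106). SPIC was at least 125-fold lower and ITGAM at least 69.4-fold, and GPNMB fell by 7.02. Of the PrE LN511 arrays, TFAP2C was above background only on replicate 1 and GPNMB only on replicate 2. In all 3491 genes passed, 1863 higher and 1628 lower. The shared spread pools the wide PrE pair on LN511 (median standard deviation 0.458) with tighter groups. Standard errors may therefore be too small on LN511 and too large on MEF. With array weights, fewer genes passed on LN511 and more on MEF, so the counts do not rank the substrates. Cholesterol synthesis passed beside the 14 lists of the average, with HMGCS1 (1.27), SQLE (1.13) and IDI1 (1.08) among 6 of 17 members that rose (adjusted p = 0.0336, but adjusted p = 0.178 with an estimated correlation), and 6 lists passed with an estimated correlation. The arrays of the shared slide gave 3798 genes. Fitted on the 4 arrays of this comparison alone, 1326 genes passed, and without naive LN511 replicate 1 or 2 there were 1361 or 1377.

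The changes on MEF and on LN511, which share no array, were set side by side over all genes. Their log2 fold changes correlated across genes with r = 0.788 and rho = 0.646, and with r = 0.800 within the shared slide. Of 4199 genes called on either substrate 93.0% had the same sign on both, and of 1645 called on both 1641 had the same direction. These were 947 higher and 694 lower genes, against 148 and 120 from independent lists of those sizes. Both lists use the same estimate of each gene's spread, so they were not independent and these 2 reference counts may be too low. The median absolute change of the 1645 genes was 2.15 on MEF and 2.58 on LN511.

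The interaction asked which genes changed differently on the substrates, and 8 genes passed. SLC12A1, the kidney Na-K-Cl cotransporter, rose at least 22.7-fold on LN511 and was not well above background in H9 on MEF in either state (adjusted p = 0.0112). PAX2, a kidney and neural transcription factor, rose at least 23.1-fold on LN511 and at least 1.30-fold on MEF, where it was above background on 1 of 2 PrE arrays (adjusted p = 0.0442). HDC, histidine decarboxylase, rose at least 16.2-fold on LN511 (adjusted p = 0.0442), GYPE at least 12.1-fold (adjusted p = 0.0442), EPDR1 at least 6.29-fold (adjusted p = 0.0451) and GYPB at least 5.33-fold (adjusted p = 0.0442). None of these 4 was well above background in H9 on MEF in either state. The 2 H9 PrE arrays on MEF had the lowest shares of spots above background of all arrays (48.3% and 42.7%). The HNES1 PrE array on MEF, which is not in this contrast, was above background for SLC12A1, PAX2, HDC and EPDR1. GYPE and GYPB are near-identical glycophorin paralogs that a probe may not separate. ALPL, tissue-nonspecific alkaline phosphatase, went from naive to PrE by 2.28 on MEF and by -2.87 on LN511 (difference -5.15 ± 0.56, adjusted p = 0.0442). ADGRB3, an adhesion receptor, fell at least 6.29-fold on LN511 and was not well above background on MEF (adjusted p = 0.0442). Only for ALPL were the changes on both substrates measured, so the sizes of the other 7 differences are not known. Within the shared slide 0 genes passed in limma, with 1703 at an unadjusted p below 0.05, against 1796 over all arrays. Leaving out PrE LN511 replicate 1 gave 561 genes and replicate 2 gave 918, and leaving out any other H9 array gave 0 to 2.

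Of the gene lists, naive pluripotency (median difference -1.30, adjusted p = 0.00222) and core pluripotency (-1.14, adjusted p = 0.0129) had changes that were lower on LN511 than on MEF, as had trophectoderm (-0.98, adjusted p = 0.00559). Fibroblast genes (1.44, adjusted p = 0.00222) and Wnt targets (0.93, adjusted p = 0.0203) had changes that were higher on LN511. With an estimated correlation each lost its call, with adjusted p = 0.449 for naive, fibroblast and Wnt genes, adjusted p = 0.516 for core genes and adjusted p = 0.41 for trophectoderm. The medians within the shared slide were -1.31, -0.90, -1.14, 1.22 and 1.07 for naive, core, trophectoderm, fibroblast and Wnt genes (adjusted p = 0.00282, 0.0198, 0.00282, 0.0117 and 0.0301). The PrE arrays on LN511 did not agree in these lists. Relative to the naive mean, the naive list lay at -4.17 on replicate 1 and at -1.44 on replicate 2, against -1.50 and -1.21 on the MEF arrays, and the core list at -1.09 and 0.23 against 0.26 and 0.45. Without PrE LN511 replicate 1 only trophectoderm passed (-1.15, adjusted p = 0.00458). The other values were then 0.09 (adjusted p = 0.287) for naive, -0.03 (adjusted p = 0.705) for core, 0.75 (adjusted p = 0.287) for fibroblast and 0.80 (adjusted p = 0.287) for Wnt genes. Without replicate 2 trophectoderm did not pass (-0.80, adjusted p = 0.131).

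**Figure D3:**
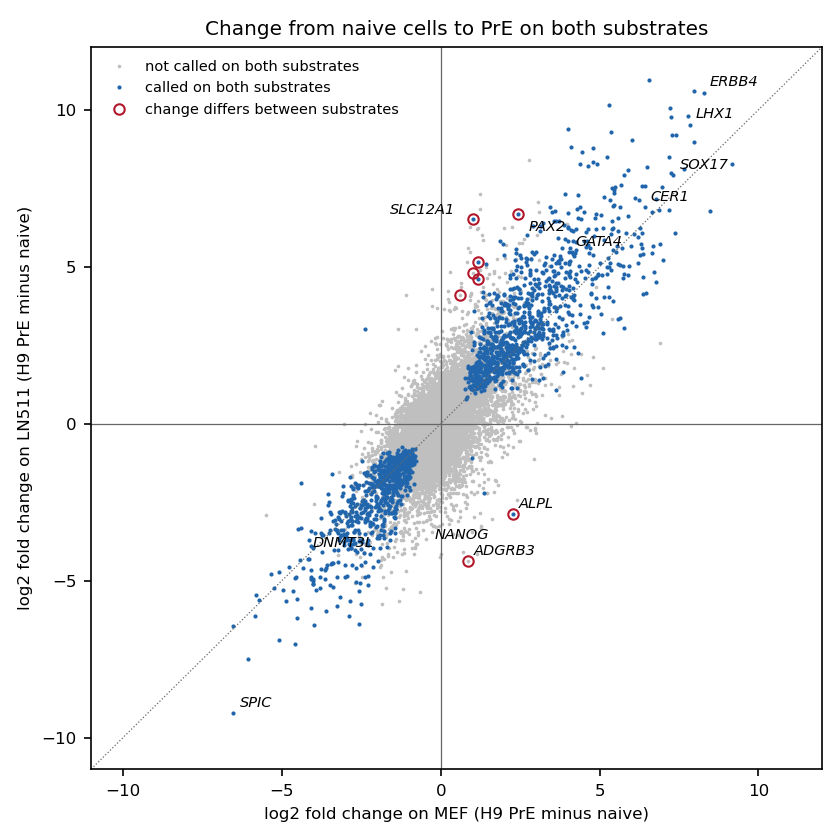
Log2 fold change from naive to PrE on LN511 (y axis) against that on MEF (x axis), 1 point per gene, with genes called on both substrates in blue and the 8 genes of the interaction circled. The points lie along the diagonal (r = 0.788), and ALPL and ADGRB3 lie below it and SLC12A1 and PAX2 above it.

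The substrate was then compared within naive cells (2 LN511 arrays against 3 MEF arrays). Fibroblast genes were lower on LN511: DCN, the proteoglycan decorin, fell by 6.42 ± 0.51 (adjusted p = 0.00761), COL1A2 by 4.47 ± 0.37 (adjusted p = 0.00761) and COL1A1 by 4.38 ± 0.46 (adjusted p = 0.0114). LOX, a collagen cross-linker, was at least 13.7-fold lower, COL8A1 at least 24.0-fold and ZEB1, a mesenchymal transcription factor, at least 18.0-fold. CGA was higher on LN511 by 5.64 ± 0.59 (adjusted p = 0.0114), CGB3, a gonadotropin beta subunit with near-identical paralogs, by 4.63 ± 0.38 (adjusted p = 0.00761) and PGF, placental growth factor, by 3.31 ± 0.45 (adjusted p = 0.0357), and CYP19A1, aromatase, was at least 3.92-fold higher (adjusted p = 0.0142). CCKBR rose by 3.73 (not above background on MEF replicate 2) and ADGRB3 was at least 5.24-fold higher. The pluripotency factors POU5F1 (-0.18), NANOG (0.43) and SOX2 (0.28) did not pass. In all 32 genes passed, 12 higher and 20 lower.

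The fibroblast list fell in naive cells on LN511, with 4 of 19 members lower (6 adjusted over the list alone; median -1.38, or -0.75 with dim genes at their bounds; adjusted p = 1.13e-10, but adjusted p = 0.0993 with an estimated correlation). The trophectoderm list rose, with 3 of 13 members higher (6 adjusted over the list alone; median 0.74, adjusted p = 2.85e-07, and adjusted p = 0.0454 with an estimated correlation). Epithelial-mesenchymal genes (median -0.65, adjusted p = 3.2e-05; 1 of 12 lower and 3 adjusted over the list alone) and basement membrane genes (-0.38, adjusted p = 8.59e-05; 0 of 20) were lower as lists, both with adjusted p = 0.0454 with an estimated correlation. Neuroectoderm genes had a median of -1.54 (adjusted p = 0.000493, but adjusted p = 0.069 with an estimated correlation), yolk sac genes one of 0.53 (adjusted p = 0.00539, but adjusted p = 0.5 with an estimated correlation) and cell cycle genes one of 0.23 (adjusted p = 0.00539, but adjusted p = 0.235 with an estimated correlation). The naive list had a median of -0.09 (adjusted p = 0.549) and the core list one of 0.29 (adjusted p = 0.279).

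Within the shared slide 0 single genes passed in limma between substrates in naive cells, with 875 at an unadjusted p below 0.05, against 1063 over all arrays. There DCN had a value of -6.04 (adjusted p = 0.0505), COL1A2 one of -4.55 (adjusted p = 0.0505), COL1A1 one of -4.37 (adjusted p = 0.0696), CGA one of 5.81 (adjusted p = 0.0545) and CGB3 one of 4.70 (adjusted p = 0.0505). The within-slide lists still passed for fibroblast (-1.21, adjusted p = 6.37e-08), trophectoderm (0.76, adjusted p = 9.43e-08), epithelial-mesenchymal (-0.51, adjusted p = 0.00058), basement membrane (-0.40, adjusted p = 0.000134), neuroectoderm (-1.39, adjusted p = 0.00157) and cell cycle genes (adjusted p = 0.0327), and not for yolk sac genes (adjusted p = 0.112). Glycolysis also passed there (-0.49, adjusted p = 0.000337), though not over all arrays (-0.14, adjusted p = 0.125). Leaving out either naive LN511 array also gave 0 single genes (566 and 433 at an unadjusted p below 0.05), naive MEF replicate 3 gave 9, either PrE MEF array 19 and either PrE LN511 array 56.

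In PrE, 2 LN511 arrays were compared with 2 MEF arrays, and 306 genes passed, 168 higher and 138 lower on LN511. The wide spread of the LN511 pair was pooled here with tighter groups, and fewer genes passed with array weights. SLC12A1 was at least 9.55-fold higher on LN511 (adjusted p = 0.00129), HDC at least 7.04-fold and CGA at least 3.92-fold, and PAX2 rose by 3.98 ± 0.35 (adjusted p = 0.00574; 1 of 2 MEF arrays above background). DKK1 (2.58 ± 0.29, adjusted p = 0.0135), the hyaluronan receptor CD44 (2.65 ± 0.46, adjusted p = 0.0405; its other measured probe 0.82, adjusted p = 0.299), SOX11 (2.50; 1 of 2 MEF arrays above background) and GATA6 (1.45 ± 0.29, adjusted p = 0.0495) were also higher. DCN fell by 6.77 ± 0.56 (adjusted p = 0.00396; 1 of 2 LN511 arrays above background), ALPL by 4.50 ± 0.41 (adjusted p = 0.00591), COL8A1 by 4.18, TFAP2C by 3.94 (adjusted p = 0.0135; 1 of 2), PRDM14 by 2.64 and the tight junction gene CLDN6 by 2.35, and LOX was at least 11.3-fold lower. COL1A1 (-2.42, adjusted p = 0.0535), SOX17 (2.47, adjusted p = 0.128), PDGFRA (2.11, adjusted p = 0.104), NANOG (-2.39, adjusted p = 0.309) and POU5F1 (-1.63, adjusted p = 0.328) did not pass. Within the shared slide 362 genes passed, with DCN at -6.77 (adjusted p = 0.0154), ALPL at -4.50 (adjusted p = 0.0154) and GATA6 at 1.45 (adjusted p = 0.0461); PRDM14 no longer passed (adjusted p = 0.0542). Leaving out PrE LN511 replicate 1 gave 2732 genes and leaving out replicate 2 gave 2096, while without naive MEF replicate 2 or 3, either naive LN511 array or either PrE MEF array there were 10 to 37. Fitted on these 4 arrays alone, 0 genes passed, with 2136 at an unadjusted p below 0.05. Median centring gave 479 genes, 338 of them higher, and normexp gave 1056, 801 of them higher.

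As lists, naive pluripotency was lower in PrE on LN511 (1 of 18 members, 3 adjusted over the list alone; median -1.42, adjusted p = 0.000487), as was glycolysis (0 of 17, 2 adjusted over the list alone; -0.72, adjusted p = 0.00565). Wnt targets (1.28, adjusted p = 0.0337), cholesterol synthesis (0.80, adjusted p = 0.0337; 0 of 17 higher over all genes and 7 adjusted over the list alone) and hypoblast genes (0.86, adjusted p = 0.0412) were higher. None of these 5 lists passed with an estimated correlation (adjusted p = 0.545) or without PrE LN511 replicate 1 (adjusted p = 0.19 to 0.609). That array alone carried the lower naive list. Without it the median was -0.18, and replicate 2 (-1.44 relative to the naive mean) lay near the MEF arrays (-1.50 and -1.21). Within the shared slide naive genes (adjusted p = 0.0009), glycolysis (adjusted p = 0.0009), cholesterol synthesis (adjusted p = 0.0321) and hypoblast genes (adjusted p = 0.0321) passed and Wnt targets did not (adjusted p = 0.0561). Under median centring Wnt targets (adjusted p = 0.0654), cholesterol synthesis (adjusted p = 0.0509) and hypoblast genes (adjusted p = 0.0725) lost their call. The fibroblast list had a median of 0.16 (adjusted p = 0.824), with 2 of 19 members lower.

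**Figure D4:**
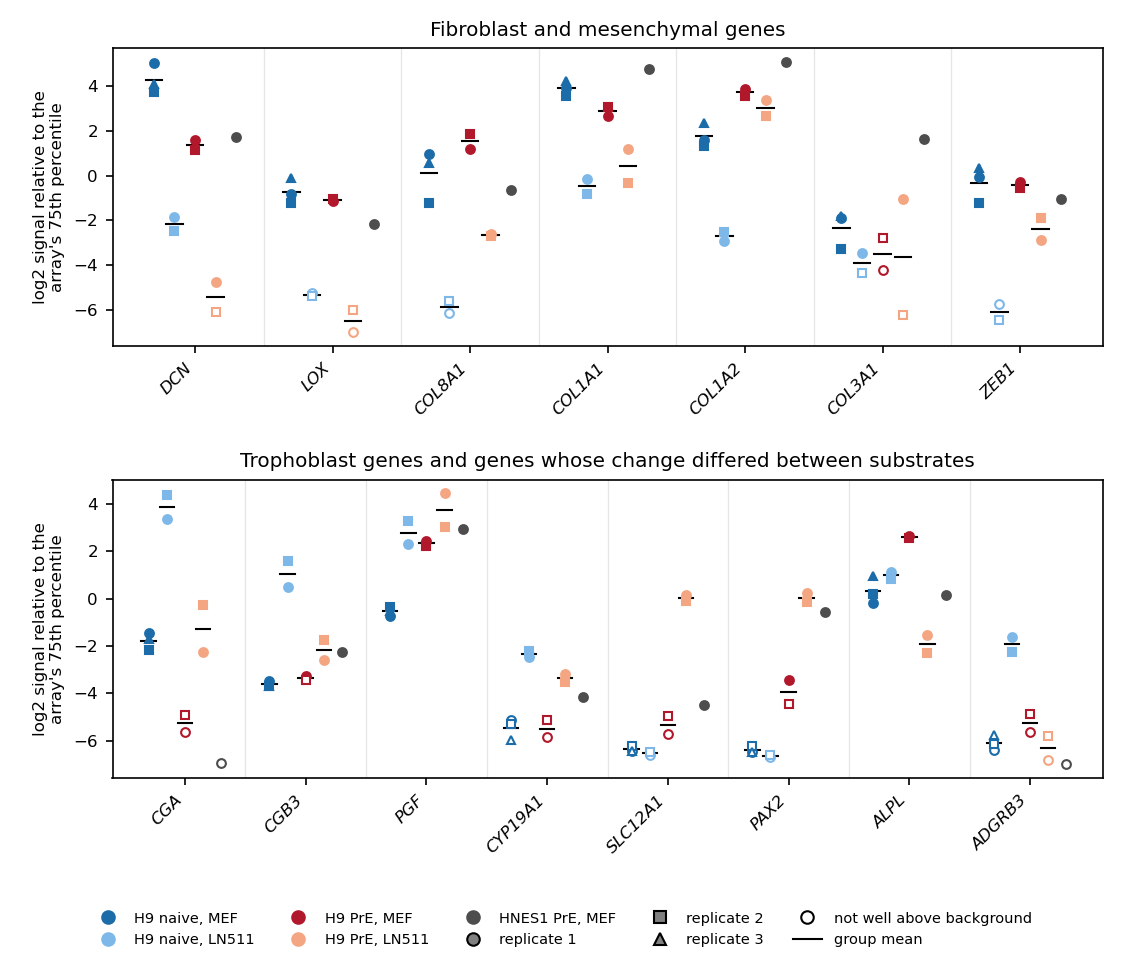
Log2 signal relative to each array's 75th percentile for 7 fibroblast and mesenchymal genes (COL3A1 did not differ between substrates by the test) and 8 trophoblast genes or genes of the interaction, 1 point per array, coloured by group, open where not well above background, with bars at group means. DCN, LOX and COL8A1 are lower on LN511 in both states, and CGA and CGB3 are higher on LN511 in naive cells.

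The last comparison set 1 HNES1 PrE array on MEF against 2 H9 PrE arrays on MEF. The lone array was assumed to vary like the others. The spread of HNES1 cannot be estimated, so the difference has no replicate check and the values describe that array rather than the line. Of single genes, SDSL, a serine dehydratase-like enzyme, was higher on the HNES1 array by 4.31 ± 0.36 (adjusted p = 0.029; 1 of 2 H9 arrays above background), and PTCHD1 was called (adjusted p = 0.0369) but not well above background in either line. A fit on the 3 arrays alone gave 0 genes, as did leaving out any naive array or either H9 PrE array on MEF, while leaving out either PrE LN511 array gave 413. SP6 (3.25, adjusted p = 0.0537) and PAGE4 (at least 4.50-fold higher, adjusted p = 0.114) had the next smallest p-values without passing. GATA4 (0.55), GATA6 (0.01), POU5F1 (-2.39, adjusted p = 0.417) and NANOG (-2.58, adjusted p = 0.499) did not pass. Among lists, basement membrane (median 1.02, adjusted p = 8.03e-06, but adjusted p = 0.0681 with an estimated correlation), hypoblast (1.39, adjusted p = 0.000317, but adjusted p = 0.267 with an estimated correlation) and fibroblast genes (1.03, adjusted p = 0.000317, but adjusted p = 0.535 with an estimated correlation) were higher on the HNES1 array. Core pluripotency was lower (-1.61, adjusted p = 0.000167, but adjusted p = 0.535 with an estimated correlation), as was the naive list (-1.22, adjusted p = 0.0158, but adjusted p = 0.632 with an estimated correlation), which lost its call under median centring (adjusted p = 0.123) and normexp (adjusted p = 0.109). Cholesterol synthesis (0.38, adjusted p = 0.00176, but adjusted p = 0.267 with an estimated correlation) changed the sign of its median under median centring, and cell cycle genes (-0.37, adjusted p = 0.0367, but adjusted p = 0.535 with an estimated correlation) lost their call under quantile normalization (adjusted p = 0.56) and normexp (adjusted p = 0.909). Median centring lowered the medians of basement membrane and fibroblast genes to 0.61 and 0.63, and normexp that of hypoblast genes to 0.81. The HNES1 array lay on another slide and scan day than the H9 PrE arrays and had no naive HNES1 array beside it. It also had the highest share of spots above background of all arrays (66.6%). The H9 PrE arrays on MEF had the lowest (48.3% and 42.7%). Line, degree of differentiation, slide, scan day and signal over background therefore cannot be told apart.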

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

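Tests of a shared share of undifferentiated cells, of dilution of endoderm RNA and of feeder RNA were chosen only after the result was seen. The reference range used in the scan-day test and the condition on members that move both ways in the dilution and feeder tests were also set after the values were seen.

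Of the genes set apart by a test of the difference between substrates, 6 had a higher fitted change on LN511 than on MEF: SLC12A1 (difference 5.52), PAX2 (4.24), GYPE (3.98), EPDR1 (3.81), HDC (3.49) and GYPB (3.45). ALPL (-5.15) and ADGRB3 (-5.24) had a lower one. Only ALPL was above background in each group. The other 7 values are fitted partly to signals at background and give no size, since PAX2 was not well above background in naive cells and the other 6 were not in H9 on MEF in either state. Among lists, the same test set apart fibroblast genes (median difference 1.44) and Wnt targets (0.93) with higher changes on LN511, and naive pluripotency (-1.30), core pluripotency (-1.14) and trophectoderm genes (-0.98) with lower ones. Neither result held throughout: within the shared slide 0 genes passed, with 1703 at an unadjusted p below 0.05, and none of the 5 lists passed with an estimated correlation (adjusted p = 0.41 to 0.516). Without PrE LN511 replicate 1 only trophectoderm genes passed: that array carried the lower naive list (-4.17 relative to the naive mean, against -1.44 in replicate 2) and core list (-1.09 against 0.23), while the MEF arrays lay at -1.50 and -1.21 and at 0.26 and 0.45. Outside the named genes, 1126 of 7113 probes with no name in the table used here passed for differentiation averaged over the substrates, 466 higher and 660 lower. No group held 4 or more arrays, so single arrays were not tested as outliers.

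The number of genes changed by differentiation averaged over substrates was set against other groupings of the same arrays. In a fit of 2 groups to the 9 H9 arrays, the real split into 4 and 5 gave 4218 genes, the highest of the other splits gave 1, and 1 of 100 splits, the real one, gave as many. Each other split puts naive and PrE arrays together in at least 1 group, so their difference enters the spread and few genes can pass. Chance between cultures cannot be judged this way, since the replicates may be technical.

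Naive MEF replicate 1 stood apart from the other naive MEF replicates, and it alone among the H9 arrays shared slide and scan day with none of them. Carry-over of feeder RNA was argued against: the fibroblast list of 19 genes differed from replicates 2 and 3 by a median of 0.37 log2 units, with an upper quartile of 0.86, below the 1 log2 unit that carry-over was set to give. For the scan day shared with the HNES1 array, the differences correlated across genes with r = 0.115, over the bound of 0.1 set for it. Replicate differences of groups that share no culture number, scanned on 1 day, reached 0.11 in absolute value. The H9 arrays subtracted on the 2 sides carry the same culture numbers. Of the groups with shared numbers, scanned on 1 day, the LN511 pair reached 0.117 and the MEF pair 0.0344. Such a correlation can thus arise without a difference in scan day, and the test cannot decide. Scan day stays open, as does the slide, which holds no other array of these groups, and no biological explanation was tested.

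The PrE replicates on LN511 differed over 2-fold in 4760 of 15421 genes, with naive genes higher in replicate 2 by a median of 1.95, core genes by 1.87 and mesendoderm genes by 2.34, and mesoderm genes lower (-1.25). By the bound written for it, a share of undifferentiated cells like the naive arrays, with other cells like replicate 1, was argued against. The share that each of 31 pluripotency genes implied had an interquartile range of 0.761, over the 0.3 set for it. Genes with a small gap between replicate 1 and the naive arrays were kept. Noise alone can widen the range there, so the range by itself cannot exclude such a share. In replicate 2, 13 of 15 primed genes lay above both replicate 1 and the naive arrays, by a median of 1.61. The 8 endoderm factors that rose were higher in replicate 2 by a median of 1.10, which by the bound written for it argued against dilution of endoderm RNA. Dilution was left undecided by a condition set after the values were seen, because these factors moved both ways (5 of 8 higher, from -1.12 to 3.01). Of 15 hypoblast genes, 10 were lower. A different stage or mix of fates in the replicates may be a biological explanation and stays open, as does a difference in culture or in RNA handling that the labels do not record.

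Fibroblast genes were lower on LN511 in naive cells, with 16 of 19 list members lower but only 4 called (6 adjusted over the list alone) and the list's call lost with an estimated correlation (adjusted p = 0.0993), and feeder RNA in the MEF samples is a candidate explanation. The list had a median of 0.16 in PrE, which by the bound written for it argued against feeder RNA in both states. Its members moved both ways there, with 7 of 19 lower, and a condition set after the values were seen made this undecided. Moreover, 11 of its 19 members rose with differentiation itself, so in PrE the list does not track feeders alone. In PrE, the 20 genes called lower on LN511 in naive cells had a median change of -2.05, with 18 of 20 lower, as feeder RNA in both states would give. The PrE arrays did not enter the naive difference of these genes, but they entered the shared spread and the choice of probes behind the calls. Hybridisation of mouse feeder RNA was not tested, since probe sequences were not used here, and a response of the human cells to the substrate stays open. Slide row and substrate cannot be told apart.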

How the results depend on the processing

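Normexp, the pooled HNES1 array, scan day as a block and the lists under other normalizations and without each array were chosen after seeing the data. Differentiation averaged over substrates kept within 1.5 times its 4979 genes under each alternative but leave-one-out fits. The other comparisons rest on few arrays, and a lone array left in a group was assumed to vary like the others. Both substrate comparisons, the interaction and the line moved with most choices. Signal over background limits folds of dim genes to bounds. Of 6147 alternative values of called named genes, 5413 kept direction and call, 733 lost the call and 1 reversed; of 6839 of uncalled ones, 494 gained a call and 70 changed sign. The reversal was CYP19A1 for substrate in PrE under normexp (-0.0117, adjusted p = 0.975). The cause was not tested for any change below, except that fewer arrays or probes were used where that is the setting. Leaving out either PrE LN511 array also removed the spread of that pair, the widest (median standard deviation 0.458), from the shared estimate. Contrasts that do not use these arrays could change only through that estimate. The counts without either array therefore do not show what that array's values did.

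Signal and normalization moved these counts. Normexp gave 10 genes for substrate in naive cells (32 in the chosen analysis), 1056 for substrate in PrE (306), 15 for the interaction (8) and 22 for the line (3). Quantile normalization gave 494 for substrate in PrE and 8 for the line, and median centring gave 479 for substrate in PrE. With no filter there were 49 for substrate in PrE, 1 for the interaction and 0 for the line (3398 at an unadjusted p below 0.05), and the correlation of the changes on MEF and LN511 was 0.735. With probes well above background on all 10 arrays, substrate in naive cells gave 13, the interaction 0 (1428 unadjusted) and the line 0 (1557 unadjusted), and the correlation was 0.745.

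Batch settings moved others. Within the shared slide, and with scan day as a block, substrate in naive cells gave 0 (875 unadjusted in both) and the interaction 0 (1703 and 1704 unadjusted). Slide as a random block gave 465 for substrate in PrE and 1 for the line. In the model, array weights gave 4956 genes on MEF (2353), 1698 on LN511 (3491), 183 for substrate in naive cells, 2 for substrate in PrE, 0 for the interaction (1395 unadjusted) and 137 for the line. The trended and robust prior gave 567 for substrate in PrE, 2 for the interaction and 1 for the line. Only the arrays of the comparison gave 1326 on LN511, 0 for substrate in PrE (2136 unadjusted) and 0 for the line (4205 unadjusted). With HNES1 pooled, the interaction gave 1 and the correlation was 0.829.

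Whether the replicate numbers pair the samples cannot be told. Deviations of same-numbered arrays correlated by -0.0603 to 0.129, with 3 of 12 pairs over 0.1, and numbers in the file names by 0.0137 to 0.117, with 2 of 4. In groups of 2 arrays the deviations mirror each other, so pairs between such groups repeat 1 value and these counts hold repeats. With label numbers as a replicate block, substrate in naive cells gave 1, substrate in PrE 10, the interaction 0 (1607 unadjusted) and the line 0 (1435 unadjusted), and the correlation was 0.765. With file-name numbers as a block, MEF gave 1400 and the interaction 0 (1505 unadjusted).

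Of the lists, an estimated correlation left 9 of 14 for the average, 6 of 15 on LN511, 3 of 7 for substrate in naive cells, 0 of 5 for substrate in PrE, 0 of 5 for the interaction and 0 of 7 for the line. Fry left 2 for substrate in PrE, 0 for the interaction and 1 for the line, median centring 2 for substrate in PrE and 8 for the interaction, and normexp 12 for the interaction. For the average, normexp gave 15 lists, but medians of 1.37 for endoderm factors (3.67 in the chosen analysis), 1.37 for primed (3.33), 1.38 for Wnt (2.85), 2.60 for mesoderm (4.74), 3.40 for mesendoderm (5.83), 1.66 for hypoblast (2.71), 2.11 for amnion (3.47), 2.42 for FGF/ERK (4.01), 0.80 for fibroblast (1.80) and 0.58 for integrin genes (1.34). For substrate in naive cells it gave -0.52 for fibroblast genes (-1.38), and neuroectoderm (adjusted p = 0.0712) and yolk sac genes (adjusted p = 0.857) lost their call. Leaving out each array gave 14 to 15 lists for the average, 15 to 16 on MEF, 14 to 17 on LN511, 7 to 9 for substrate in naive cells, 0 to 8 for substrate in PrE, 1 to 11 for the interaction and 6 to 7 for the line, with the 0 and the 1 without PrE LN511 replicate 1.

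Leaving out each array in turn gave 3168 to 6487 genes for the average, 673 to 4152 on MEF, 1361 to 5070 on LN511, 0 to 56 for substrate in naive cells, 10 to 2732 for substrate in PrE, 0 to 918 for the interaction, 0 to 413 for the line and 0.728 to 0.800 for the correlation, lowest without PrE LN511 replicate 2. For the interaction, the counts of 0 had 1017 to 1703 genes at an unadjusted p below 0.05. For the line, either PrE LN511 array left out gave 413 and any other H9 array 0 (1087 to 2305 unadjusted). Not run were normexp on the mean signal, which the files lack, the deposited table in the same fit, since it holds group means, the file-name block for substrate and line, and the shared slide for the line.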

Other observations

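CGA fell from naive cells to PrE on LN511 by 5.13 (adjusted p = 0.00126) and was at least 2.74-fold lower on MEF, where neither H9 PrE array was above background. PGF rose on MEF by 2.87 (adjusted p = 0.00503) and had a value of 0.96 on LN511 (adjusted p = 0.19). VGLL1, a cofactor expressed in trophoblast, was at least 7.47-fold lower in PrE on LN511. In naive cells on LN511, further genes were higher than on MEF: NOS2, nitric oxide synthase, at least 5.71-fold, CA8 at least 3.98-fold, CAPN6 by 1.96 (adjusted p = 0.0357) and the fibrinogen chain FGG by 1.65 (adjusted p = 0.038), while NFIB, a nuclear factor, was at least 7.76-fold lower and FZD2 fell by 4.62 (adjusted p = 0.0322). Of the naive MEF arrays, FGG was above background only on replicate 3.

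In PrE, other genes that were higher on LN511 included the synaptic cadherin CLSTN2 (at least 8.17-fold), the fatty acid elongase ELOVL2 (at least 5.38-fold) and the glycophorin GYPE (at least 5.08-fold), and the nucleotide receptor P2RY2 rose by 3.73. Of the H9 PrE arrays on MEF, P2RY2 was above background only on replicate 1. RNF183, a ubiquitin ligase, was at least 9.93-fold lower, the matrix protease MMP3 at least 5.52-fold lower, and the tubulin TUBB4A fell by 4.08 and EPPK1 by 4.06. Of the PrE arrays on LN511, EPPK1 was above background only on replicate 1. Of the 32 genes called between substrates in naive cells, 8 were called lower on LN511 in both states and 2 higher in both. Among the 12 higher ones, 8 were also higher in PrE, with a median of 0.96.

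The authors' deposited table holds 4798 entries, the last of them incomplete, with ranks up to 32494. Its mean for PrE on MEF matched the mean of the 2 H9 arrays and the HNES1 array, with a standard deviation of the difference of 0.0169 log10 units, against 0.108 without the HNES1 array. Its mean for naive cells on MEF differed from the 3 arrays by 0.0863 log10 units, against 0.0159 and 0.0178 for the LN511 groups, and the cause was not tested.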
